A study of Mus musculus with 4 samples.

How the data were processed

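RNA was measured in 4 libraries of mouse bone-marrow-derived macrophages that the labels put in 1 group as biological replicates 1 to 4. Per the labels' protocols the RNA was polyA selected. For each library the deposited files held a gene table and a transcript table with expected counts and TPM in the column layout of RSEM, and a second transcript table with estimated counts and TPM in the column layout of kallisto. Per the deposited notes, all tables were made on the mm10 assembly with the GENCODE M21 annotation, the first 2 from an alignment to the transcriptome and the third straight from the read files. The programs and their versions are not given in the sources used here, so RSEM and kallisto are names read from the column layout. Per the file headers, TPM are scaled within each library, and the deposited expected counts carry no normalization. The deposited notes list 6 read files for replicates 1 and 2 and 4 read files for replicates 3 and 4. Raw reads were not used here.

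The gene lists, gene pairs, tests, alternatives and the rule for named genes were chosen before the data were examined. Gene rows were joined to GENCODE M21 by identifier (55536 genes); 97 spike-in rows and 26248 tRNA rows were left out of gene totals and tests. Gene counts totalled 25594340, 27384162, 48875472 and 57126810, so that 3 counts, the most that a count of 0 allows, correspond to 0.117, 0.110, 0.0614 and 0.0525 CPM. These limits cover counting error only. Levels are RSEM TPM, given as mean ± SD over the 4 libraries. A list's level in a library is the median over its members of log2(TPM + 1). A pair's value is log2((TPM a + 1)/(TPM b + 1)) within a library. List differences and pairs were tested by exact sign-flip permutation over the 4 libraries, which cannot give a p below 0.125, and the pairs were adjusted by the Benjamini-Hochberg method. The list median in TPM is the median over members of the mean TPM.

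Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr with a minimum count of 10, quasi-likelihood fits, Benjamini-Hochberg threshold 0.05). The biological coefficient of variation came from a design with an intercept alone, in which each gene's quasi-dispersion was also tested against the abundance trend with an F statistic. The plan called for a comparison of libraries only if the files recorded a technical difference splitting them 2 against 2. It named run type, read length, strandedness and processing. The number of read files, which is not among these, was taken as such a difference, and what it reflects is not known. Replicates 3 and 4 were therefore compared with replicates 1 and 2. Fold changes are log2 of replicates 3 and 4 over replicates 1 and 2. Their SE was derived as the absolute fold change over the square root of the quasi-likelihood F statistic. DESeq2 1.42.0 (Wald test) was the alternative tool. Adjustment over a list alone used the edgeR p-values of its tested members. GC content and length came from GENCODE M21 transcripts, and offsets per library were fitted by loess; this correction and 3 other alternatives for the split were added after the data were seen. Genes were called discordant if the TPM summed over transcripts differed at least 2-fold between the 2 quantifications in all 4 libraries. The edgeR comparison of the libraries, the edgeR test of variable genes and the coefficient of variation were tested on simulated counts with known changes; the other tests were not. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

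Named genes followed these rules: the 10 genes of highest mean TPM; in each list the 3 members of highest mean TPM and all members of pairs; list members and the 10 leading genes among any called more variable; the 3 genes of largest discordance in each direction; the 10 called genes of largest fold change in each direction with a mean of at least 5 TPM, and all called list members; the 3 list genes with the largest and the smallest difference in main transcript share; and the sex-linked genes. Genes named in the text outside these rules were chosen after their values were seen. Alternatives were other normalizations, filters, pseudocounts, quantifications and tools, and leaving out each replicate in turn. No paired analysis of conditions was possible because the series has 1 group. Replicates 1 and 3 against 2 and 4 were also fitted with the pairs of libraries as a block, a fit added after the data were seen. Sting1 had no gene under that name and was left out, while Tmem173, its older name, was used.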

Results

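These macrophages were taken 12 h after a lipid A pretreatment had been washed out. By mean TPM, ferritin RNA was the most abundant of protein-coding nuclear genes. Interferon-stimulated genes formed, on average, the most abundant of the lists. Fth1 and Ftl1, which encode the ferritin chains that store iron, and B2m, the light chain of class I molecules, were among the most abundant. Saa3, an acute-phase protein made by activated macrophages, and Ccl5, a chemokine that attracts T cells and monocytes, stood at a similar level. Tnf, Il1b and Nos2, classical products of lipid A stimulation, stood far below them.

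The series holds polyA-plus RNA-seq of bone-marrow-derived macrophages from C57BL/6J mice, in 1 group of 4 replicates. Per the labels, cells were pretreated with 100 ng/ml lipid A for 12 h, washed out for 12 h and collected at 0 min of a restimulation. Other label fields name the pretreatment lipoprotein A. No untreated or singly stimulated cells belong to the series, so no value below is an effect of the pretreatment. Expected gene counts added up to 25594340, 27384162, 48875472 and 57126810 in replicates 1 to 4. The replicates are separate biosamples that carry the same donor identifier, so p-values over libraries measure the spread between these libraries only. Xist, expressed from the inactive X chromosome, had 44.7, 78.2, 79.0 and 58.1 TPM, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had 0 TPM in all 4 libraries, where 0 counts allow up to 0.117, 0.110, 0.0614 and 0.0525 CPM in replicates 1 to 4.

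Of 55536 genes, 10476 had at least 1 TPM in every library and 12261 in at least 1 library. The 10476 held 9797 protein-coding genes, 123 lincRNAs and 313 pseudogenes. By mean TPM over the 4 replicates (± SD), the leading protein-coding nuclear genes were Fth1 (54786.1 ± 16250.8), B2m (17389.9 ± 1665.1), Ftl1 (15939.3 ± 6884.0), Saa3 (15788.0 ± 4144.1), Ccl5 (15092.0 ± 9035.9) and Tmsb4x (12825.0 ± 4553.2), which encodes an actin-binding peptide. The mitochondrial genes mt-Atp8 (25323.6 ± 20345.3) and mt-Co1 (11954.1 ± 6660.5) were also among the leading 10, together with the rRNA gene CT010467.1 and Gm28661, a copy of mitochondrial sequence on chromosome 1 whose reads cannot be told from mitochondrial ones with certainty. CT010467.1 ranged from 3125.5 TPM in replicate 3 to 84919.8 TPM in replicate 1.

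Macrophage identity genes were strongly expressed in every replicate. Lyz2, the macrophage lysozyme, and the lysosomal proteases Ctsd and Ctsb led the list. All 20 genes had a row, 19 of them had a mean of at least 10 TPM, and 17 at least 100 TPM. Lyz2 had 9726.3 ± 1479.4, Ctsd 7654.4 ± 1111.8 and Ctsb 7069.1 ± 1819.2 TPM. Cd14, the coreceptor that passes lipid A to TLR4, had 128.4 ± 39.78 TPM. The exception was Cx3cr1, the fractalkine receptor of monocytes and tissue macrophages, at 0.383 ± 0.335 TPM, a gene singled out after its values were seen.

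By the mean over replicates, interferon-stimulated genes formed the most abundant of the 23 lists, with a median over members of 608 TPM; the macrophage identity list stood higher in replicate 1 (median log2(TPM + 1) of 9.277 against 9.064) and level with it in replicate 4 (9.047 against 9.046). Ifit2 and Ifit3, interferon-induced proteins that act against viral RNA, had 2751.2 ± 499.4 and 2309.6 ± 737.6 TPM, and Isg15, a ubiquitin-like modifier, had 2471.2 ± 1351.9 TPM. Of 26 members, 23 had at least 100 TPM. Ifi44l, singled out after its values were seen, was the only member below 1 TPM, at 0.0075 ± 0.015.

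Antimicrobial genes were abundant while most inflammatory cytokine genes were not. Saa3 and Acod1, the enzyme that makes itaconate, stood high, and so did the chemokines Ccl5, Cxcl10 and Ccl7. Il23a, a subunit of interleukin 23, was near the limit of detection. The antimicrobial list had a median of 410 TPM over 20 genes, with Acod1 at 1086.9 ± 573.3 TPM. The cytokine list had a median of 22.0 TPM over 26 genes, of which 20 reached 1 TPM and 7 reached 100 TPM. Besides Ccl5, these included Cxcl10 (1441.1 ± 881.3), Ccl7 (942.8 ± 760.4), Ccl2 (865.2 ± 757.3), Ccl3 (675.5 ± 295.4), Ccl4 (662.6 ± 628.3) and Tnf (208.3 ± 128.4). Il1b had 65.55 ± 39.32, Nos2 17.48 ± 15.68, Il12b 8.20 ± 1.51 and Il23a 0.205 ± 0.324 TPM. The median log2(TPM + 1) of the cytokine list lay below that of the antimicrobial list by 4.62 ± 0.92 in all 4 libraries (difference -4.62, exact sign-flip permutation p = 0.13, the smallest value that 4 libraries allow, 2 of 16 sign assignments). The mean difference was -3.97 in replicates 1 and 2 and -5.27 in replicates 3 and 4, and -2.72 over all replicates when only members with at least 1 TPM were used.

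Genes of alternative activation were low. Tgfb1, a cytokine that restrains inflammation, and Il4ra, the interleukin 4 receptor, were the most abundant of them, whereas Arg1, the arginase induced by interleukin 4, was almost absent. The list had a median of 4.06 TPM over 18 genes, and 11 reached 1 TPM. Tgfb1 had 235.2 ± 59.52, Il4ra 133.6 ± 17.98, Cd36, a scavenger receptor for lipids, 94.03 ± 57.15, Mrc1 41.59 ± 5.568 and Arg1 0.09 ± 0.135 TPM. The inflammatory list stood above the alternative list by 1.57 ± 0.82 log2 units (exact sign-flip permutation p = 0.13), by 2.15 in replicates 1 and 2 and 0.99 in replicates 3 and 4.

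All listed components of the lipid A receptor pathway and most of its brakes were expressed. Ikbke, a kinase upstream of interferon production, Cd14 and Myd88, the adaptor of most Toll-like receptors, led the receptor and proximal signalling list. In it all 24 genes reached 1 TPM and 18 reached 10 TPM. Ikbke had 220.3 ± 47.48, Myd88 121.7 ± 22.63 and Tlr4 39.0 ± 6.59 TPM. Among 19 negative regulators, 17 reached 1 TPM and 15 reached 10 TPM: Il1rn, the interleukin 1 receptor antagonist, had 363.9 ± 167.7, Atf3, a repressor of cytokine genes, 339.1 ± 98.6, Tnip3, an inhibitor of NF-kB, 148.7 ± 37.79 and Irak3, an inactive kinase that restrains Toll-like receptor signalling, 53.35 ± 14.43 TPM. Of the 11 NF-kB and IkB genes, Nfkbia, the inhibitor that NF-kB induces itself, had 194.4 ± 120.4, Rela 96.63 ± 65.2 and Nfkb1 63.33 ± 12.74 TPM. The other pattern receptors had a median of 70.3 TPM, led by Tlr1 (184.9 ± 35.84), Tlr13 (155.2 ± 43.6) and Tlr8 (139.4 ± 36.33).

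By list medians, but not clearly by list means, glycolytic transcripts stood slightly above those of the TCA cycle and respiratory chain. Gapdh, Pkm and Aldoa led the first list, and Atp5b, Cox5a and Cox4i1, subunits of ATP synthase and cytochrome c oxidase, led the second. Gapdh had 1504.6 ± 546.6, Pkm 536.3 ± 64.32, Atp5b 524.5 ± 76.77 and Cox5a 391.8 ± 257.1 TPM. The difference between list medians was 0.76 ± 0.17 log2 units (exact sign-flip permutation p = 0.13), 0.89 in replicates 1 and 2 and 0.63 in replicates 3 and 4, and 0.12 ± 0.15 (exact sign-flip permutation p = 0.5, without a common sign in the 4 libraries) when members were averaged instead. Antigen presentation genes had a median of 157 TPM, with H2-K1 at 7692.1 ± 605.1 and H2-D1 at 4484.8 ± 799.0 TPM. In RSEM a retained-intron transcript, H2-K1-215, took 33.9 to 61.3% of the H2-K1 TPM. The oxidative stress list (median 51.7 TPM) was led by Prdx1, a peroxide-reducing enzyme, at 1638.4 ± 348.6 TPM, Sqstm1, an autophagy receptor, at 867.6 ± 366.2 TPM and Hmox1, which degrades heme, at 463.6 ± 72.49 TPM. Nr1h3 (126.7 ± 27.89), Abcg1 (117.1 ± 21.39) and Abca1 (71.54 ± 7.461), the LXR alpha receptor and 2 of its cholesterol-exporting targets, led the cholesterol list (median 41.1 TPM). Cell cycle genes had a median of 2.75 TPM, with Pcna, the DNA replication clamp, at 265.6 ± 68.33 and Cdk1, the mitotic kinase, at 27.0 ± 7.44 TPM. Of the Cdk1 TPM, 51.8 to 67.0% belonged in RSEM to a retained-intron transcript, Cdk1-204.

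Markers of other cell types were nearly silent, with few exceptions. The list medians were 0.605 TPM for neutrophils and their precursors, 0.237 for dendritic cells, 0.113 for T and NK cells, 0.101 for B cells, 0.0975 for fibroblasts, 0.0625 for mast cells and basophils, 0.04 for endothelium and 0 for erythroid cells. Csf3r, the G-CSF receptor, had 130.3 ± 39.66 TPM, Cd4 49.02 ± 24.73 TPM and Kdr, a VEGF receptor, 15.42 ± 11.37 TPM. S100a8 and S100a9, the calprotectin subunits of neutrophils and monocytes, had 34.8 and 48.2 TPM in replicate 1, 4.67 and 8.36 in replicate 2, 20.7 and 47.6 in replicate 3, and 2.31 and 3.76 in replicate 4.

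**Figure D1:**
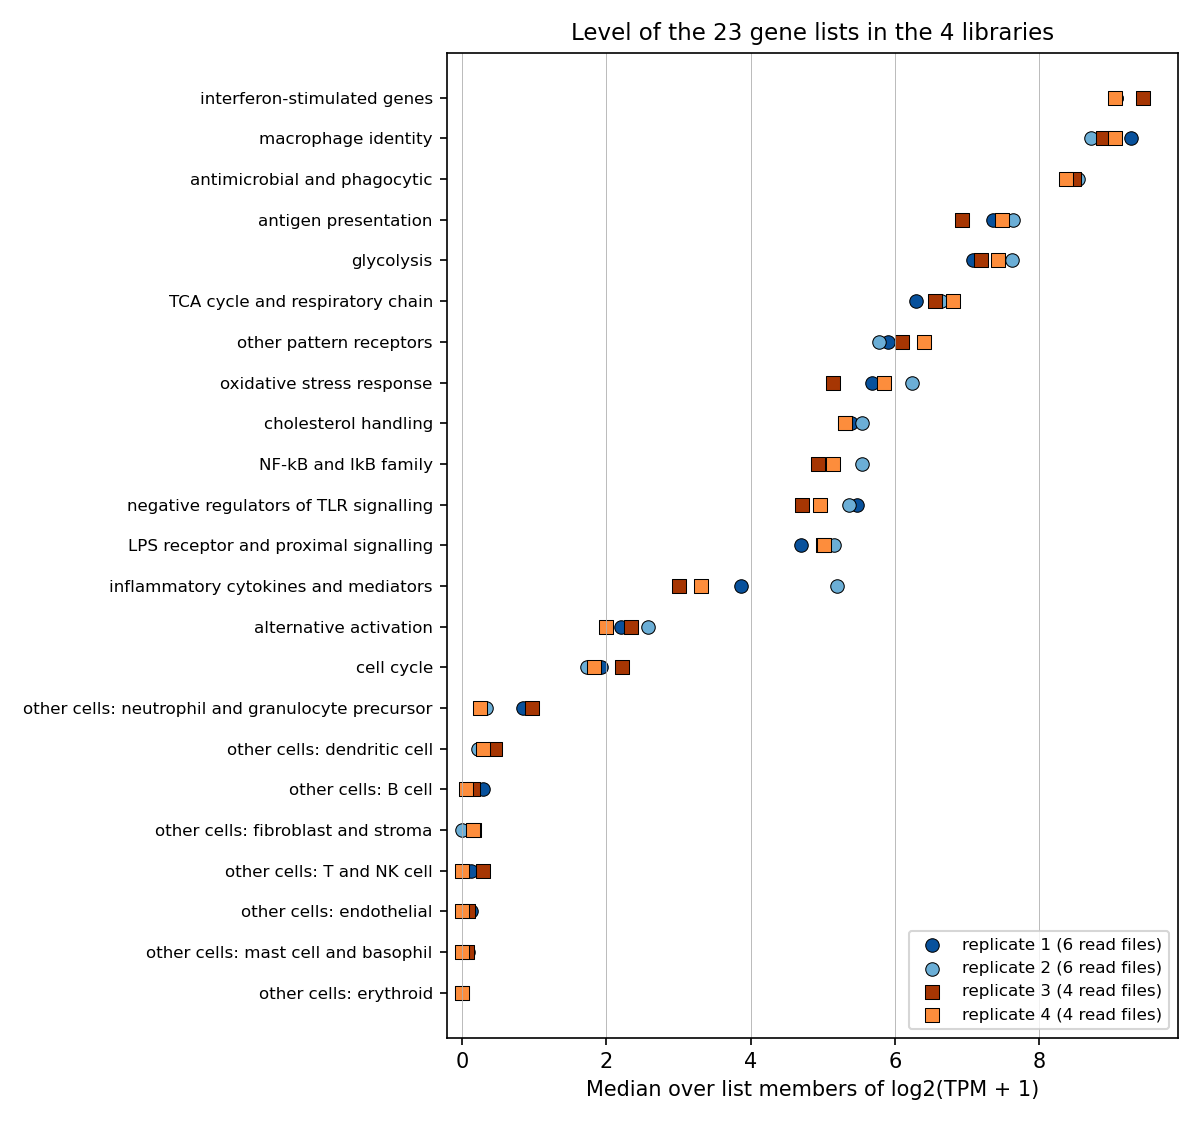
Median over list members of log2(TPM + 1) for the 23 gene lists in replicates 1 to 4. Circles are libraries made from 6 read files and squares are libraries made from 4.

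Ratios of gene pairs within each library placed inflammatory products against their counterparts. Nos2, the inducible nitric oxide synthase, exceeded Arg1 in every library, and Tnf exceeded Il10, an anti-inflammatory cytokine. Il1b lay below its antagonist Il1rn, and Irak3 and Irak2 lay above Irak1. Of 14 pairs, 12 kept the same sign in all 4 libraries. Arg1 and Il23a had 0 to 14 counts per library, so that the pseudocount set the ratios of Nos2 over Arg1 and Il12b over Il23a. Their mean log2 ratios were 3.74 and 2.95 with a pseudocount of 1 (3.41 and 2.25 with kallisto TPM) and 6.36 ± 1.64 and 5.23 ± 1.00 with a pseudocount of 0.1, so their sign was the same in every library and their size is not known. For the other pairs the mean log2 ratio was 2.72 ± 0.96 for Tnf over Il10, -2.57 ± 1.11 for Il1b over Il1rn, 0.66 ± 0.35 for Irak3 over Irak1 and 0.93 ± 0.25 for Irak2 over Irak1. It was 2.23 ± 0.51 for Myd88 over Ticam1, the adaptor of the interferon branch, 0.92 ± 0.50 for Tlr2 over Tlr4, 0.81 ± 0.43 for Cd86 over Mrc1, -1.93 ± 0.67 for Hk2 over Hk1 and -3.83 ± 0.44 for the protease genes Ctsl over Ctsb. Cxcl10 over Cxcl9 had 4.99 ± 2.01, with 6.69 in replicates 1 and 2 and 3.29 in replicates 3 and 4. The 2 pairs without a common sign also differed between those pairs of libraries: Nfkb1 over Rela had 0.67 and -1.39 (mean -0.36 ± 1.21, exact permutation p = 0.625; by counts, Rela differed between the pairs of libraries by 0.38 and Nfkb1 by -0.16, neither called by edgeR) and Ccl3 over Ccl4 had -0.26 and 1.33 (mean 0.54 ± 0.99, exact permutation p = 0.375). For the other 12 the exact permutation p was 0.13, which cannot be lower with 4 libraries (0.146 after adjustment over the pairs).

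The libraries resembled each other most within the pairs 1 and 2, and 3 and 4. Across genes, the correlation of log2(TPM + 1) was 0.969 between replicates 1 and 2, 0.981 between replicates 3 and 4, and 0.933 to 0.945 between the pairs. The biological coefficient of variation was 0.295 over the 4 libraries and 0.211 within the pairs. It was 0.238 for replicates 1 and 2 and 0.186 for replicates 3 and 4. No gene varied more than others of its abundance by the edgeR test (0 of 11991 at adjusted p below 0.05, 528 at unadjusted p below 0.05, lowest adjusted p 0.951; no other tool was run). In simulated data the test recovered 45.5% of genes whose dispersion was raised 10 times. All other simulated genes lay on the abundance trend, so recovery in the real libraries may be lower.

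Genes of several chemokines and of inhibitors of inflammatory signalling differed between replicates 3 and 4 and replicates 1 and 2. Ccl2, Ccl3, Ccl4 and Ccl5, which attract monocytes and T cells, and Cxcl10 and Cxcl11, ligands of CXCR3, were lower in replicates 3 and 4. So were Nfkbia and Nfkbie, inhibitors of NF-kB, Socs1, a brake on cytokine receptors, and Cebpb, a transcription factor of the macrophage inflammatory response. The mitochondrial gene mt-Nd4l, a subunit of complex I, was higher. This was a comparison of libraries with different numbers of read files, not of conditions. The deposited notes list 6 read files for replicates 1 and 2 and 4 for replicates 3 and 4. The labels name no difference in treatment.

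Of 11991 tested genes, 696 differed at an edgeR adjusted p below 0.05, 250 higher and 446 lower in replicates 3 and 4 (3415 at unadjusted p below 0.05, 600 expected by chance). DESeq2 called 1866, among them all 696. With offsets for GC content and length, 579 were called, 284 higher and 295 lower, so the excess of lower genes shrank; 460 of the 696 stayed called and all 696 kept their direction. The lower genes were short and GC-rich (median 1281 nt and 55.06% GC) beside all tested genes (2540 nt and 49.78%). In simulated data 54% of genes with a log2 fold change of 1 were recovered and 100% of those with 2. All simulated genes had the dispersion of the abundance trend, and only the more abundant were changed. Recovery in the real libraries may therefore be lower. Cxcl2, picked after its values were seen, did not pass at a log2 fold change of -2.46 (edgeR adjusted p = 0.123). The libraries also differed in make-up along the same split: mitochondrial genes took 0.778, 1.16, 3.34 and 3.00% of counts in replicates 1 to 4, and the total in kallisto over that in RSEM was 1.314, 1.323, 1.073 and 1.062. The other 2 ways to split the libraries 2 against 2 gave 0 genes with edgeR (342 and 73 at unadjusted p below 0.05) and 30 and 0 with DESeq2. With the pairs of libraries as a block, replicates 1 and 3 against 2 and 4 gave 0 genes with edgeR (1127 at unadjusted p below 0.05) and 186 with DESeq2.

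Most inflammatory cytokine genes had lower counts in replicates 3 and 4. Of 20 tested members, 19 had a negative fold change, with a median log2 fold change of -1.71 (-1.68 with the offsets). Over all genes, 7 fell and 0 rose by edgeR and 13 fell and 1 rose by DESeq2; 15 fell and 1 rose by edgeR when adjusted over the list alone. The 7 were Ccl5 (chromosome 11: 83525778 to 83530518 in mm10; log2 fold change -1.66, SE 0.24, adjusted p = 0.0342), Ccl4 (-2.83, SE 0.40, 0.0329), Ccl2 (-2.58, SE 0.46, 0.0423), Cxcl11 (-2.88, SE 0.29, 0.0224), Cxcl10 (-1.56, SE 0.21, 0.0326), Il1b (-1.55, SE 0.26, 0.0389) and Ccl3 (-1.16, SE 0.19, 0.0369). Ccl5 had 21613.8, 24111.0, 7713.8 and 6929.3 TPM in replicates 1 to 4. Tnf (-1.34, SE 0.27, adjusted p = 0.0502) and Nos2 (-1.76, SE 0.48, 0.0809) did not pass, nor did Cxcl9, a CXCR3 ligand induced by interferon gamma and the only member with a positive fold change (1.29, SE 0.34, 0.0755).

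**Figure D2:**
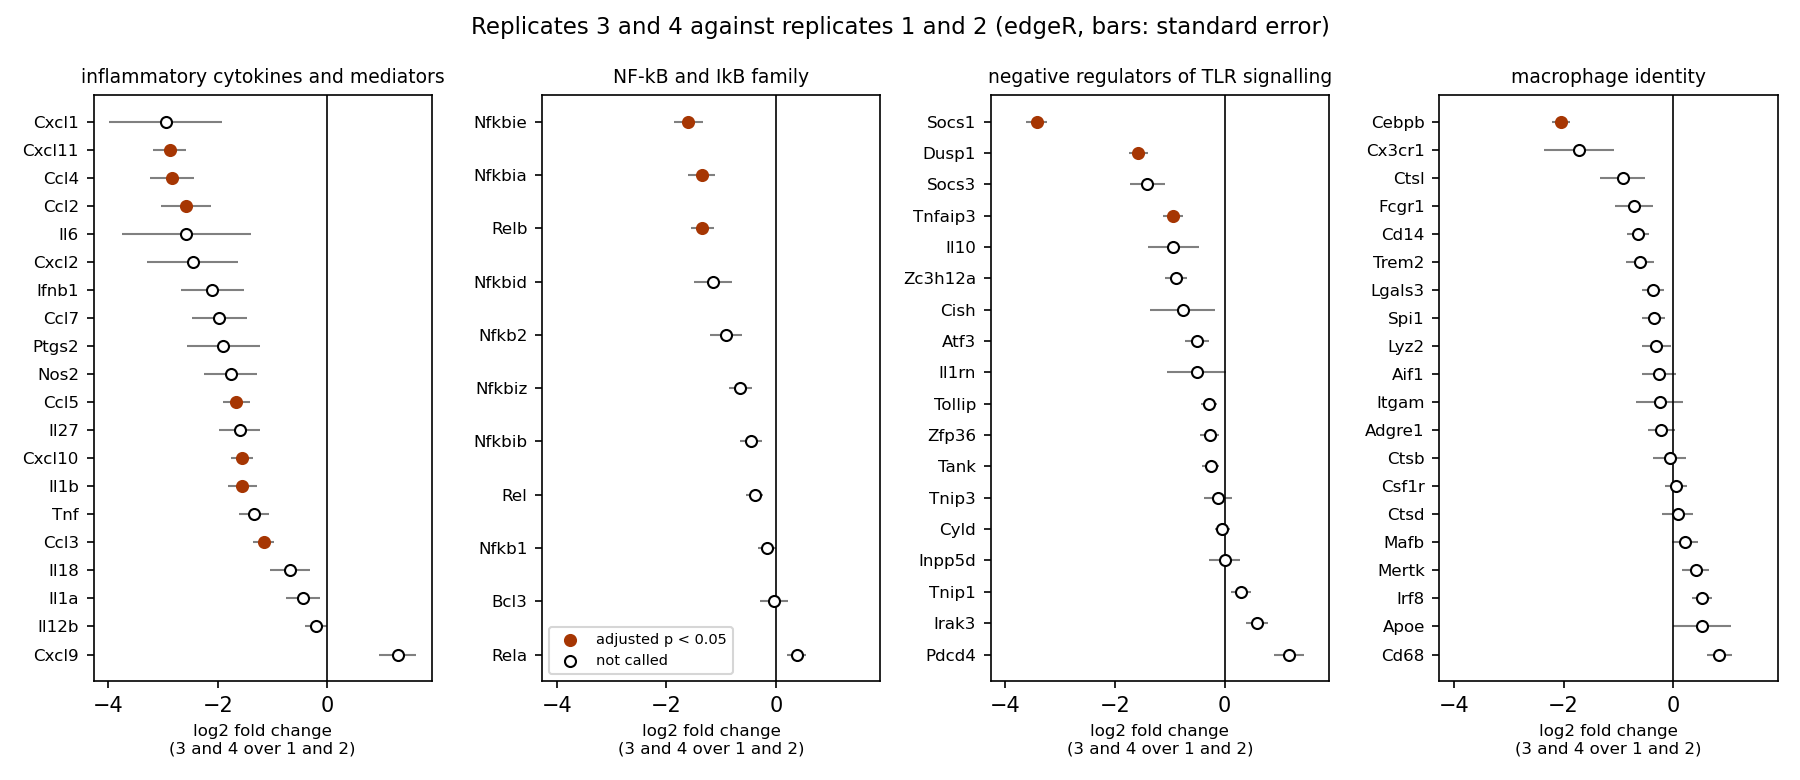
Log2 fold change (edgeR, bars give the standard error derived from the F statistic) of tested members of 4 gene lists, replicates 3 and 4 over replicates 1 and 2. Filled points have an adjusted p below 0.05.

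Some NF-kB family genes and negative regulators fell in the same replicates. Of 11 NF-kB and IkB genes, 3 fell and 0 rose by edgeR (6 and 0 adjusted over the list alone; 5 and 0 by DESeq2): Nfkbie (-1.60, SE 0.26, adjusted p = 0.0368), Nfkbia (-1.36, SE 0.25, 0.0437) and Relb, an NF-kB subunit (-1.34, SE 0.21, 0.0358). With the GC and length offsets Relb did not pass, at a fold change of -0.95 (SE 0.18). Of 18 negative regulators, 3 fell and 0 rose by edgeR (5 and 1 adjusted over the list alone, 5 and 1 by DESeq2): Socs1 (chromosome 16: 10782240 to 10785536; -3.43, SE 0.19, adjusted p = 0.0144), Dusp1, a phosphatase that switches off MAP kinases (-1.57, SE 0.17, 0.0248), and Tnfaip3, which encodes the ubiquitin editor A20 (-0.94, SE 0.18, 0.0454). Socs1 had 13.85 and 17.48 TPM in replicates 1 and 2, and 1.46 and 1.37 in replicates 3 and 4. Il1rn (-0.50, SE 0.54) and Irak3 (0.59, SE 0.20, adjusted p = 0.124) did not pass.

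Single members changed in the other inflammatory lists. Among 25 interferon-stimulated genes, Bst2, which tethers virions (-1.78, SE 0.23, adjusted p = 0.0323), Isg15 (-1.49, SE 0.24, 0.0368) and Usp18, which removes ISG15 (-1.17, SE 0.24, 0.0496), fell and 0 rose by edgeR (5 fell and 1 rose adjusted over the list alone, 6 fell and 2 rose by DESeq2), while the list's median fold change was -0.30; with the offsets Usp18 kept its fold change (-1.18, SE 0.23) at an adjusted p of 0.0525. Among 19 antimicrobial genes, Fpr2, a formyl peptide receptor (-1.67, SE 0.20, adjusted p = 0.0298), and Sod2, the mitochondrial superoxide dismutase (-1.13, SE 0.21, 0.0447), fell and 0 rose by edgeR (4 fell adjusted over the list alone, and 4 by DESeq2). Among 16 antigen presentation genes, Psmb9, an immunoproteasome subunit (-0.86, SE 0.16, adjusted p = 0.0432), and Cd40, a costimulatory receptor (-1.15, SE 0.23, 0.0493), fell and 0 rose by edgeR (5 fell adjusted over the list alone, and 6 by DESeq2); with the GC and length offsets 0 of the 16 passed, Psmb9 at -0.67 (SE 0.15) and Cd40 at -0.89 (SE 0.25).

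In the identity, glycolysis and respiratory lists 1 gene each passed the edgeR threshold, which 696 of 11991 tested genes passed. The lists are too small to tell their share from that of all genes. DESeq2 called 1866 genes in all. Of 20 identity genes only Cebpb fell by edgeR (chromosome 2: 167688915 to 167690418; -2.05, SE 0.16, adjusted p = 0.0166; also the only member adjusted over the list alone), and 0 rose; with the offsets its fold change was -1.25. DESeq2 called 3 identity genes, 1 higher and 2 lower. Pgk1, a glycolytic kinase (-1.005, SE 0.17, adjusted p = 0.037), was the only 1 of 17 glycolysis genes to pass (2 fell adjusted over the list alone), and Cox5a (-1.85, SE 0.19, 0.0228) the only 1 of 16 TCA cycle and respiratory genes, also adjusted over the list alone. DESeq2 called 5 glycolysis genes, 1 higher and 4 lower, and 2 TCA cycle and respiratory genes, 1 higher and 1 lower. Among genes of other cell types Cd4, a T cell coreceptor also found on some macrophages, rose (1.31, SE 0.25, adjusted p = 0.0457), with a fold change of 1.27 (SE 0.26) and an adjusted p of 0.053 with the offsets.

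Receptor, repair and proliferation lists had no member past the edgeR threshold, which 696 of 11991 tested genes passed. At that share lists of 10 to 24 genes hold few calls, so 0 calls do not set a single list apart. DESeq2 called 1866 of all genes. By edgeR 0 of 24 lipid A receptor and signalling genes passed over all genes or adjusted over the list alone (8 at unadjusted p below 0.05; 6 called by DESeq2), for example Tlr4 (-0.29, SE 0.23) and Myd88 (-0.42, SE 0.21). The counts were 0 of 12 for alternative activation (3 at unadjusted p below 0.05; 2 by DESeq2), where Mrc1 had 0.15, SE 0.22, and 0 of 14 for other pattern receptors (2; 1 by DESeq2), where Tlr8 had -0.10, SE 0.35. They were 0 of 10 for oxidative stress genes (3; 2 by DESeq2), where Hmox1 had -0.20, SE 0.27, 0 of 11 for cholesterol genes (4; 2 by DESeq2), where Abca1 had 0.24, SE 0.20, and 0 of 15 for cell cycle genes (0; 0 by DESeq2), where Pcna had -0.30, SE 0.34. In these 5 lists 0 also passed when adjusted over the list alone. With the GC and length offsets Tgfb1 rose (1.02, adjusted p = 0.0457), and Chuk, an IkB kinase (-0.90, 0.0442), and Nlrp3, an inflammasome sensor (-0.85, 0.0495), fell, the latter 2 named after their values were seen.

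The largest fold changes belonged mostly to ribosomal protein copies and pseudogenes, whose counts are uncertain because their reads also fit the parent genes. Among the lower genes, Lars2, the mitochondrial leucyl-tRNA synthetase, is not such a copy (-3.47, SE 0.30, edgeR adjusted p = 0.0187). It had 374.4, 274.9, 29.22 and 29.34 TPM in replicates 1 to 4. Whether its reads also fit other sequences was not tested. The other lower genes were Pgam1-ps2 (-3.96), Socs1, Rpl9-ps6 (-3.21), Gm12918 (-3.21), Rps12-ps3 (-3.20), Rpl28-ps1 (-3.12), Rps13-ps1 (-3.07, but 3.86 with kallisto counts), Rpl23a-ps3 (-2.99) and Cxcl11. The higher genes were led by Gm49369, a protein-coding locus at chromosome 7: 142371096 to 142382667 with no established function (8.22, SE 0.46, adjusted p = 0.0144; 9.73, 7.28, 1893.6 and 3269.6 TPM). It overlaps Ctsd on the same strand (142375911 to 142388038), so its reads cannot be assigned with certainty either. They also held mt-Nd4l (2.60, SE 0.24, adjusted p = 0.0187; 287.4, 519.7, 2770.6 and 2566.0 TPM), Gm45140 (2.99) and the pseudogenes Gm2541 (3.90), Gm10095 (3.82), Gm12715 (3.79), Rps6-ps4 (3.12), Rps12l1 (2.85), Gm14328 (2.63) and Rpl36a-ps2 (2.58).

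The 2 deposited quantifications of each library, in the layouts of RSEM and kallisto, differed at least 2-fold in every library for several small RNAs and many gene copies and for none of the listed genes. Mir6236, Gm24270 and Gm24245, annotated as microRNAs, had estimates in kallisto alone, and Klf10, a transcription factor induced by TGF-beta, differed most among protein-coding genes. Of 12757 genes compared, 593 differed at least 2-fold in the same direction in all 4 libraries, 446 higher in kallisto and 147 higher in RSEM. They held 188 pseudogenes, 79 of 10498 protein-coding genes and 0 list members, although 40 of 153 named genes moved by over 1 SD with kallisto. Mean TPM in RSEM and kallisto was 0 and 57478 for Mir6236, 0 and 9318 for Gm24270 and Gm24245, 696 and 0 for Gm10222, 869 and 1.28 for Gm10076, and 269 and 0 for Gm10443. Klf10 had 17.5 and 44697, mt-Atp6 137 and 7204, and the ribosomal protein gene Rps12 518 and 17.4 TPM, 3 genes looked at after the count had been seen.

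The main transcript of most listed genes was the same in both quantifications. Nos2, Ptgs2 and Tnf had the smallest difference in its share, and Relb, Pfkfb3, an activator of glycolysis, and Idh3a, a TCA cycle enzyme, the largest. Of 188 genes with at least 10 TPM and 2 or more transcripts, 167 (88.8%, 95% interval 83.5 to 92.6%) had the same leading transcript. It took a median of 76.6% of the gene's TPM, and over 90% in 72 genes. The transcript that led in RSEM took 68.2% in RSEM and 21.2% in kallisto for Relb, 49.6% and 5.76% for Pfkfb3, and 62.2% and 27.4% for Idh3a, and in kallisto another transcript led each of these 3 genes.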

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

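The tests of the split between replicates 1 and 2 and replicates 3 and 4 were chosen only after that result was seen, while those of the cytokine genes and of the Klf10 transcript were written down before their values were computed. Apart from a smaller number of neutrophil-lineage cells, no biological explanation was tested, because the design gives 1 group.

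Lower RNA of chemokine genes such as Ccl5 and Ccl4 in replicates 3 and 4 was part of a difference in 696 genes. With rRNA, mitochondrial and pseudogene counts left out, 541 genes were still called. Most calls were protein-coding (220 of 250 higher, 403 of 446 lower), so this step could remove few of them and decides little. With GC and length offsets 66.1% of the 696 (460 genes) stayed called in the same direction. The offsets follow smooth trends with GC and length of each gene's main transcript. Such trends alone did not remove the split, but other effects of GC content or length cannot be excluded. Chance could not be excluded by counting splits, since only 1 of 3 possible splits gave as many calls (the highest other gave 0) and 3 splits are too few. The share of phiX174, a control added at sequencing, was at least 2.9 times higher in replicates 1 and 2 than in replicates 3 and 4. A difference in sequencing run may therefore coincide with one in culture, and the 2 could not be separated here.

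Within that difference, the median log2 fold change of 20 inflammatory cytokine genes was -1.71, the lowest of the lists with tested genes. Of 10000 random lists matched on abundance, GC content and length, 0 were as low (95% of them lay between -0.25 and 0.29). The random lists were not matched on shared regulation, so their spread may be too narrow for genes that move together. They also allow for no choice among the lists. The comparison therefore bears on abundance, GC content and length alone. It cannot tell how often a list of co-regulated genes would be as low. For neutrophil-lineage cells, the median of 4 measured genes was 0.05, which lay 1.76 above that of the cytokine genes. The SE of 0.44 covers the neutrophil genes alone, taken as independent. These genes cannot decide whether fewer such cells account for the lower cytokine genes. S100a8 (-0.88, SE 1.226) and S100a9 (-0.231, SE 1.245) were imprecise. Csf3r (0.358, SE 0.168) stood apart from the list, with a mean of 130.28 TPM against a list median of 0.605 TPM. Of 9 dendritic cell genes (list median 0.237 TPM), the 4 tested had a median log2 fold change of -0.98 (-0.63 with GC and length offsets), 3 of them with unadjusted p below 0.05 and 0 called by edgeR or DESeq2, and an explanation by dendritic cells was not tested.

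Klf10 had 44697 TPM in kallisto and 17.5 in RSEM through the 326 nt transcript Klf10-204, which holds a run of 33 A. Its estimated counts were 253537, 363979, 4379 and 1624 in replicates 1 to 4. Of 113 transcripts with an internal run of at least 31 A, 41.59% (47) had 10 times the RSEM count, against 4.27% (92) of 2157 transcripts matched on length (Fisher exact p = 2.29e-30, transcripts taken as independent, Klf10-204 among them). Reads of poly(A) tails assigned to such runs are likely to contribute, and kallisto levels of Klf10 should not be read as expression.

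Dixon's test flags about 1 in 20 sets of 4 values by chance; it picked 14 of 191 sets, 7 for a value of replicate 1, 5 of replicate 2, 2 of replicate 3 and 0 of replicate 4. In replicate 1, rRNA took 9.01% of counts (0.351 to 1.09% in the others), protein-coding genes 89.61% (96.84 to 97.16%) and the 10 most abundant genes 27.12% of TPM (19.73 to 20.69%). The rRNA gene CT010467.1 had 84919.8 TPM in replicate 1 and 3125.5 to 10124.0 in the others. These flags are not independent, since the rRNA reads of replicate 1 enter each of these measures. Also far from the others in replicate 1 were Myd88 over Ticam1 (2.99, others 1.90 to 2.04), Dcn, a matrix proteoglycan of fibroblasts (0.55 TPM, others 0.02 to 0.07), and Klf10 in RSEM (25.01 TPM, others 14.23 to 15.58). Replicate 2 had the most genes with at least 1 TPM (11666), more TPM of Il23a (0.69, others 0.03 to 0.05), Batf3, a dendritic cell transcription factor (5.97, others 2.61 to 3.01), and Ptgs2, the inducible cyclooxygenase (33.09, others 3.26 to 7.21), and a fibroblast list median of 0. Replicate 3 had a higher median of interferon-stimulated genes (9.443, others 9.046 to 9.067) and 0.06 TPM of Hba-a2, a hemoglobin gene (0 in the others). Dcn, Il23a and Hba-a2 stayed below 1 TPM in every library, so their flags rest on values near the floor.

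The counts of phiX174 were 32827, 34059, 20989 and 23921 in replicates 1 to 4. ERCC sequences had 7, 6, 6 and 5 estimated counts in kallisto and 0 in RSEM, which does not show that they were added.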

How the results depend on the processing

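The alternatives with GC and length offsets, with rRNA, mitochondrial and pseudogene counts left out, with protein-coding genes alone, with a minimum fold change and within the 2 pairs were chosen only after the data were seen. The means of the 3 list differences kept their direction under every alternative. The cytokine difference stayed between -5.27 and -2.72, and the inflammatory against alternative difference between 0.99 and 2.15. The glycolysis difference stayed between 0.12 (members averaged, exact sign-flip permutation p = 0.5) and 0.89. The number of detected genes stayed between 7818 and 11289 and the share of genes with the same main transcript between 88.8 and 91.0%. The median correlation between libraries (0.944) moved to 0.917 with a pseudocount of 0.1 and to 0.983 with no filter on low values. With no filter on counts, 45 genes instead of 0 were more variable than the trend and 2569 instead of 696 separated replicates 3 and 4, and DESeq2 called 1866; the cause was not tested. Leaving out a replicate gave 0 to 671 genes: 177 without replicate 1, 671 without replicate 2 and 0 without replicate 3 or 4 (edgeR 1955 and 1966 at unadjusted p below 0.05; DESeq2 called 372 and 284). Each of these 4 fits has 1 library on a side, assumed to vary like the other 2. Without replicate 3 or 4 the spread came from replicates 1 and 2 alone. Their coefficient of variation was 0.238, against 0.186 for replicates 3 and 4. Why the counts differ was not tested. Of 49 named genes of the split, all 49 stayed called with DESeq2, 40 with the GC and length offsets, 34 without replicate 1, 46 without replicate 2 and 0 without replicate 3 or 4, and 33 of 39 with kallisto counts. Rps13-ps1 reversed with kallisto counts (log2 fold change 3.86 instead of -3.07), and Nfkb1 over Rela ranged from -0.742 to 0.049 with a replicate left out, reversed without replicate 4; the cause was not tested. Discordant genes numbered 976 with a pseudocount of 0.1 (cause not tested), and 366 at a mean of at least 5 TPM and 79 among protein-coding genes, where fewer genes were compared. Levels of 40 of 153 named genes moved by over 1 SD with kallisto. Thinning all libraries to the smallest left 668 genes in the split, 630 of them shared, so the difference in depth changed the calls little.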

Other observations

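Beyond the listed genes, several genes of lysosomal proteins were abundant, beside genes of actin, thymosin and ribosomal proteins. The 40 protein-coding genes of highest mean TPM outside the lists included Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages (9648.0 ± 6869.7 TPM), Psap, the precursor of the saposins (8727.0 ± 952.8), the cathepsin genes Ctss (4831.0 ± 633.8) and Ctsz (2984.1 ± 567.6), Grn, progranulin (2515.9 ± 238.1), and Lgmn, an asparaginyl protease (2319.5 ± 442.5). Complement C1q chains (C1qb 2905.0 ± 251.5, C1qc 2014.2 ± 549.1), the pore-forming protein gene Mpeg1 (2018.7 ± 198.3) and Ifitm3, which blocks viral entry (3345.9 ± 1237.6), belonged to the same set. Among noncoding RNAs, AW112010, which is induced in activated macrophages, had 1654.5 ± 592.1 TPM and Malat1, a nuclear RNA, 1070.9 ± 831.8 TPM. Malat1 had 294.82 and 410.6 TPM in replicates 1 and 2, and 1841.85 and 1736.31 in replicates 3 and 4 (edgeR log2 fold change 0.88, SE 0.22, adjusted p = 0.068). Gpnmb had 3945.54, 4377.81, 11887.25 and 18381.34 TPM in replicates 1 to 4 (edgeR log2 fold change 0.689, SE 0.287, adjusted p = 0.184). For both genes TPM differed by more than counts, so the size of the TPM difference should not be read as one in expression. These genes were chosen after their values were seen.

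Within each pair of libraries some of the same genes differed in the same direction, although tested gene by gene replicates 1 and 3 against replicates 2 and 4 gave 0 genes with edgeR (342 at unadjusted p below 0.05) and 30 with DESeq2. With the pairs as a block, which leaves 1 residual degree of freedom, they gave 0 with edgeR (1127 at unadjusted p below 0.05) and 186 with DESeq2. Of 28 protein-coding genes with at least 10 TPM that differed at least 2-fold the same way in both pairs, 8 were higher in replicates 1 and 3, among them S100a8, S100a9, Cd36 and Folr2, the folate receptor of resident macrophages (66.88, 21.43, 84.10 and 40.59 TPM in replicates 1 to 4). The other 20 were higher in replicates 2 and 4. They included C3, the central complement component (225.3, 615.2, 476.8 and 1060.7 TPM), Csf1, the macrophage growth factor (16.37, 77.65, 20.87 and 49.05 TPM), S100a4, a calcium-binding protein (22.73, 73.63, 16.38 and 80.42 TPM), and Asns, asparagine synthetase (10.25, 33.36, 12.50 and 31.48 TPM). Across 12261 genes the difference of replicates 1 and 2 correlated with that of replicates 3 and 4 with r = 0.169; of 109 genes with a 2-fold difference in both, 79 had the same direction and 30 the opposite. These genes were chosen after their values were seen.

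Some transcripts of listed genes took a larger part of the gene in replicates 3 and 4. In 18 of 188 genes a transcript had a share at least 20 percentage points higher in both of these libraries than in both others, in both quantifications. In 12 of the 18 it was under 1000 nt long. Transcripts with a higher share in replicates 1 and 2 were not counted. How many of all transcripts of these genes are that short was not compared. In replicates 1 to 4, Atf3-202 took 0, 0, 64.6 and 67.2% of Atf3 in RSEM and 25.2, 22.4, 66.0 and 70.4% in kallisto. Rela-203, a retained-intron transcript, took 12.7, 7.4, 46.0 and 46.2% of Rela in RSEM and 25.5, 20.4, 47.3 and 47.9% in kallisto, and Tlr6-202 took 44.5, 41.9, 80.9 and 87.0% of Tlr6 in RSEM and 55.8, 52.9, 80.3 and 86.8% in kallisto. For Rela the gene's TPM was higher in replicates 3 and 4 by a log2 ratio of 1.77, whereas its counts differed by 0.38 (SE 0.18, edgeR adjusted p = 0.222). For Tlr6 the values were 1.53 and 0.02 (SE 0.16, edgeR adjusted p = 0.953). For Atf3 they had opposite signs, 0.693 and -0.505 (SE 0.216, edgeR adjusted p = 0.194). The TPM levels of such genes, and their SD over the 4 libraries, thus also carry a shift between transcripts. How many genes this concerns was not counted.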
